A study of Homo sapiens with 6 samples.

How the data were processed

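RNA of A549 cells was measured in 6 libraries, 3 from cells given 5 µM anlotinib and 3 from cells given DMSO, both for 48 h. Per the labels, RNA was extracted with Trizol and libraries were made with a SMARTer mRNA kit. The aligner, the counting tool, their versions and the strand setting are not given in the sources used here. The submitters' processing notes name the build mm9, a mouse assembly. The deposited table instead holds human gene identifiers, and the coordinates of all 30483 genes equal those of GENCODE release 29 on GRCh38, which is the build used for every position given here. Of these identifiers, 30251 were found in the gene name table.

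The authors deposited 1 table of 30483 genes that held all 6 libraries, and 5 further files that repeated single libraries with identical values. The expression columns are a signal, namely normalized counts that the authors made by dividing the reads of each gene by 1 size factor per library, as the values show: every value is a whole multiple of 1 step per library, to within 1e-06 for 100% of values. The deposited size factors differed from median-of-ratios factors by at most 0.004%. The deposited table also holds the authors' log2 fold change and the authors' p-value and adjusted p-value for anlotinib against DMSO. The adjusted p is exactly 1 for 13003 genes. DESeq2 run on the recovered reads called 3179 genes, all of the 3179 called in the authors' deposited table, with log2 fold changes that differed by at most 4.1e-06 among them. Genes with fewer than 2 reads in total do not occur in the table.

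The test was limma-trend on log2(normalized count + 1) with treatment as the only term, for the 15734 genes with a mean of at least 10 normalized counts over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design fixed before the data were examined assumed either raw counts, with edgeR, or FPKM-like values, with limma and a minimum mean of 1. The files held size-factor-normalized counts, so limma was used. The minimum of 10 was chosen after the unit was known and before any test was run, and a minimum of 1 was added as an alternative. Tests on the recovered whole reads with edgeR, DESeq2 and limma-voom served only as alternatives, and edgeR called 3765 genes. The step of anlotinib replicate 1 is so near 1 that an automatic check of units could not tell its values from rounded ones, though they are multiples of it like the others. The counts of genes changed and changed at least 2-fold, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

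The 22 gene lists held 575 symbols, of which 567 were matched, 18 of them through the gene identifier. Lists with at least 5 tested members, 21 in all, were tested with camera at a preset correlation of 0.01, with the correlation estimated, and with fry. Further lists were written after a first look at the results and are used only among the other observations. Genes were named by rule: the 5 largest increases and 5 largest decreases among genes that passed, had a mean of at least 100 and did not overlap between groups, the 2 members of each list with the smallest p, and RHOA, ROCK1 and ROCK2. This gave 52 genes, of which 49 passed; some of them are not reported here. Other list members are named as examples and were chosen after their values were seen. Single values per library were compared with exact permutation tests, whose smallest two-sided p for 3 against 3 is 0.1.

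The depth of 13886120 to 15386107 reads makes 1 read worth 0.887 to 1.07 normalized counts. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom of 3.75 to 6.33 between DMSO libraries and 9.24 to 20.4 between anlotinib libraries, so no library was counted as a duplicate. The procedure was tested on simulated data for this comparison, with 100 genes changed at each size among 15786. limma recovered 87 genes changed by 1 and 43 changed by 0.5 on the log2 scale and called 5 unchanged genes. Far fewer genes were changed than were called in the data, and both groups were given the same spread. These recoveries are therefore not the sensitivity of the real comparison. With camera 0 of 20 unchanged lists were called. The simulated genes varied independently and these lists were drawn at random. The list result therefore says nothing about lists of genes that vary together. Genes that share near-identical sequence, such as tubulins, and genes that overlap on either strand are uncertain, since the counting could split or share their reads. Alternatives covered the pseudocount, the low-value filter, scaling by RLE, TMM or library totals, the count tests, a block for replicate number and leaving out each library. No sample was left out. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.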

Results

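RNA sequencing was carried out on A549 cells, an established line from a human lung adenocarcinoma. The cells had been exposed for 48 h to 5 µM anlotinib or to the solvent DMSO. Anlotinib is an oral inhibitor of several receptor tyrosine kinases, among them the VEGF, FGF and PDGF receptors and KIT. Each group held 3 libraries. The DMSO libraries held 13886120, 15212087 and 14800020 reads assigned to genes, and the anlotinib libraries 15238575, 15386107 and 15047663. Values are normalized counts, given as mean ± SD with n = 3, and fold changes are on the log2(normalized count + 1) scale, which understates the change of genes with few reads. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The largest component of variation, with 57.9% of the variance, separated the treatments. Anlotinib replicate 1 lay nearest to DMSO on it, at 19.1 against 36.2 and 41 for the other anlotinib libraries.

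**Figure D1:**
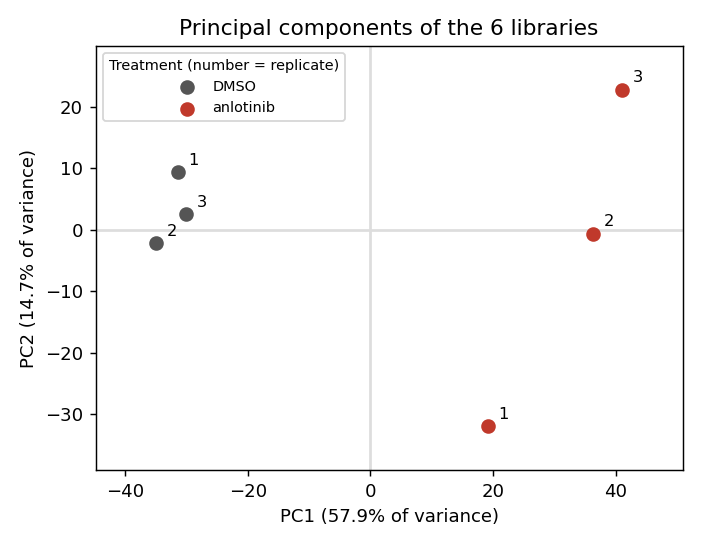
First and second principal components of log2(normalized count + 1) in the 6 libraries, colored by treatment and numbered by replicate; axes give the share of variance. The DMSO libraries lie between -34.9 and -30.1 on the first axis and the anlotinib libraries between 19.1 and 41.

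The comparison addressed which genes respond to anlotinib in tumor cells, with the extracellular matrix and RhoA/ROCK signalling as the stated interest of the series. After anlotinib, 24 of 25 genes of cholesterol synthesis and uptake, 19 of 22 p53 targets and 22 of 35 lysosome and autophagy genes rose, while 23 of 35 cell cycle genes, 9 of 19 collagens and 22 of 33 integrin and focal adhesion genes fell. Each of these lists shifted against other genes with camera at a preset correlation. None passed with the correlation estimated (in the same order, adjusted p = 0.13, 0.13, 0.2, 0.3, 0.29 and 0.2 with an estimated correlation). That setting rests on 4 residual degrees of freedom and has little power here. A list that did not pass with it is neither shown to shift nor shown not to. HMGCS1, which makes the HMG-CoA used by the mevalonate pathway, rose 6.13-fold, from 747 ± 56.6 to 4577 ± 155 (n = 3 per group). COL1A1, a chain of type I collagen, was 5.49-fold lower, at 462 ± 150 against 2482 ± 390 (n = 3 per group). Of 15734 genes tested with limma, 3648 changed at a Benjamini-Hochberg adjusted p under 0.05, 1645 higher and 2003 lower with anlotinib. With scaling by library totals the split was 2068 higher and 1552 lower. At least 2-fold changes were found for 829 genes, 465 higher and 364 lower. With a minimum mean of 50, which tests fewer genes, there were 486, and more of them were lower, with 202 higher and 284 lower. The groups did not overlap for 6329 genes, or 40.2% of those tested, where chance gives 10%. The authors' deposited table lists 3179 changed genes, 1403 higher and 1776 lower. Of these, 3063 were also called here, 0 of them in the opposite direction, and 585 genes were called here alone. The number of changed genes was 2320, 2272 and 2328 without DMSO replicates 1, 2 and 3, 5487 without anlotinib replicate 1 and 1972 without anlotinib replicate 2.

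Genes with large increases among well-expressed genes served different functions. EGR1, an immediate early transcription factor (chromosome 5, 138465490 to 138469315), rose 8.82-fold, from 39.7 ± 11.6 to 363 ± 117 (limma adjusted p = 5.13e-06). IFITM10 (chromosome 11, 1732410 to 1750591) rose 7.08-fold, from 32.6 ± 6.26 to 234 ± 19.4 (adjusted p = 8.73e-07), and shares its strand with an overlapping gene. HMGCS1 lies on chromosome 5 at 43289395 to 43313512 (adjusted p = 7.62e-09). GDF15, a stress-induced cytokine (chromosome 19, 18374731 to 18389176), rose 5.49-fold, from 1103 ± 31.4 to 6086 ± 693 (adjusted p = 1.14e-08). All coordinates are on GRCh38 and cover the whole annotated gene, with exons, introns and untranslated regions.

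The largest decreases included secreted proteins and a TGF-β feedback gene. NPTX1, a neuronal pentraxin (chromosome 17, 80467148 to 80477843), was 9.88-fold lower, at 486 ± 94.3 against 4755 ± 311 (limma adjusted p = 1.09e-08). IL11, a cytokine of the IL-6 family (chromosome 19, 55364389 to 55370463), was 9.16-fold lower, at 112 ± 5.07 against 1059 ± 292 (adjusted p = 1.22e-07). FAM111B (chromosome 11, 59107185 to 59127410) was 7.38-fold lower, at 62.7 ± 12.1 against 464 ± 45 (adjusted p = 2.58e-07). PMEPA1, a TGF-β-induced inhibitor of TGF-β signalling (chromosome 20, 57648392 to 57711536), was 7-fold lower, at 1972 ± 331 against 13767 ± 1774 (adjusted p = 4.81e-08). The long noncoding RNA gene NKILA (chromosome 20, 57710183 to 57712780) fell by 3.25 on the log2 scale (adjusted p = 7.22e-06). NKILA overlaps PMEPA1 on the opposite strand, and no strand-specific counting is stated, so reads of the pair cannot be told apart there.

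**Figure D2:**
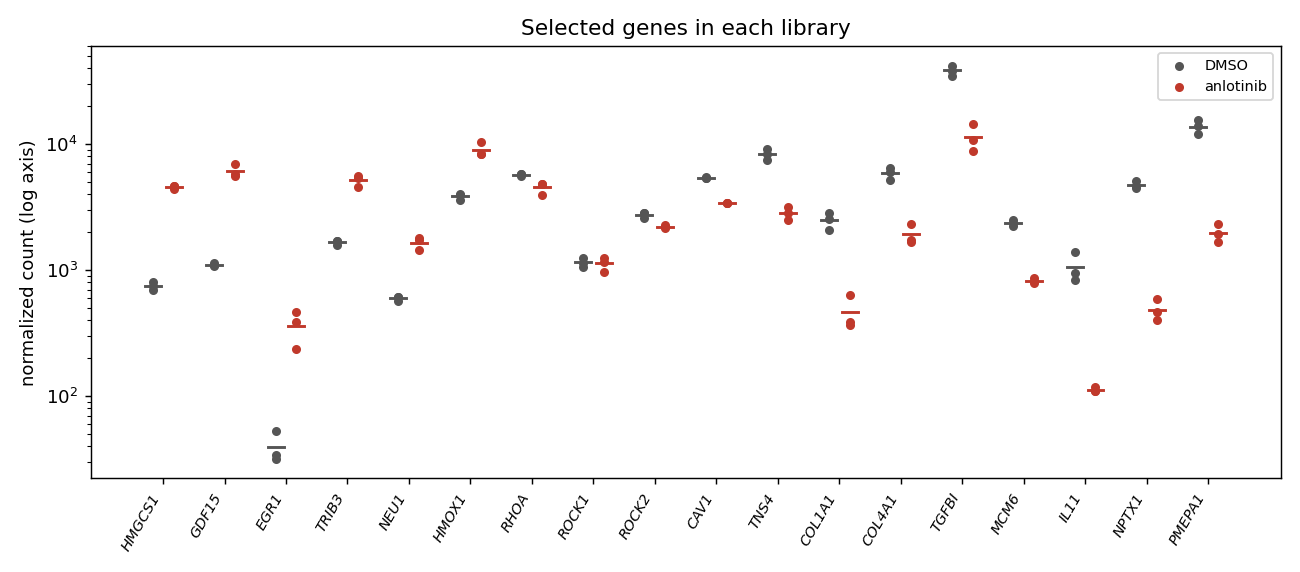
Normalized counts of 18 named genes in each library on a log axis; points are the 3 libraries of each treatment and bars their means. HMGCS1 rises from a mean of 747 to 4577 and NPTX1 falls from 4755 to 486, while the groups overlap for ROCK1.

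Part of the collagen genes and of the other matrix genes fell after anlotinib. Of 19 collagen genes tested, 9 fell, 0 rose and 10 did not pass, also 9 and 0 when adjusted over the list alone. COL4A1, a chain of the basement membrane collagen IV, fell by 1.63 (SE 0.13) on the log2 scale (limma adjusted p = 4.28e-06), and overlaps COL4A2 on the opposite strand. The fibrillar collagen gene COL5A1 fell by 1.91 (adjusted p = 2.33e-05). The list's median was -0.49 and its shift against other genes passed with camera (adjusted p = 9.48e-07), but not with the correlation between its genes estimated (adjusted p = 0.29 with an estimated correlation). Among 29 matrix glycoproteins and proteoglycans, 13 fell, 2 rose and 14 did not pass, with 15 lower and 2 higher adjusted over the list alone. TGFBI, a secreted matrix protein, was 3.45-fold lower, and HAS3, a hyaluronan synthase, 1.84-fold lower. SPP1, encoding osteopontin, rose by 0.77 on the log2 scale, and FN1, encoding fibronectin, stood at -0.04 (adjusted p = 0.798). This list had a median of -0.32 (camera adjusted p = 0.000192; adjusted p = 0.47 with an estimated correlation). Of 33 matrix remodelling and crosslinking enzymes, 9 fell, 1 rose and 23 did not pass, with 10 lower and 2 higher adjusted over the list alone. TGM2, a protein-crosslinking transglutaminase, was 3.38-fold lower, and PLOD2, a lysyl hydroxylase, fell by 0.99 on the log2 scale. The median was -0.21 (camera adjusted p = 0.0027; adjusted p = 0.51 with an estimated correlation).

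Most of the tested genes that connect cells to the matrix fell after anlotinib, as did most tested targets of the transcription factors that respond to adhesion and actin. Of 33 genes of integrins and focal adhesions, 22 fell and 1, the kinase gene SRC, rose, or 24 and 2 adjusted over the list alone. The adaptor gene TNS4 was 2.93-fold lower and CAV1, encoding caveolin-1, 1.59-fold lower. ITGAV, the integrin αV subunit, fell by 0.68 on the log2 scale. The median was -0.44 (camera adjusted p = 1.09e-08; adjusted p = 0.2 with an estimated correlation). Among 24 YAP/TEAD and SRF target genes, 14 fell and 1 rose, or 17 and 2 adjusted over the list alone. TPM1, an actin-binding tropomyosin, was 3.05-fold lower, CYR61 (CCN1), a matricellular protein gene, 2.24-fold lower, and ACTB, encoding β-actin, fell by 0.73, while ANKRD1 rose by 1.65. The median was -0.43 (camera adjusted p = 7.04e-06; adjusted p = 0.2 with an estimated correlation).

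In the RhoA/ROCK and actomyosin list, 10 of 35 genes fell, 3 rose and 22 did not pass, with 13 lower and 4 higher adjusted over the list alone. RHOA, the GTPase itself (chromosome 3, 49359145 to 49412998), was 1.26-fold lower, at 4550 ± 509 against 5712 ± 91.2 (n = 3 per group; limma adjusted p = 0.0263). ROCK2, one of the kinases it activates (chromosome 2, 11179761 to 11348330), was 1.24-fold lower, at 2213 ± 57.6 against 2752 ± 153 (adjusted p = 0.0165). ROCK1 (chromosome 18, 20946906 to 21111851) had 1128 ± 142 against 1153 ± 96.7, a log2 fold change of -0.04 (adjusted p = 0.844), which was 0.04 with scaling by library totals. ARHGEF2, a microtubule-bound activator of RhoA, was 1.49-fold higher. MYH9, the heavy chain of non-muscle myosin IIA, fell by 0.68. The median of the list was -0.18 (camera adjusted p = 0.0456; adjusted p = 0.47 with an estimated correlation). The call was also lost with edgeR (adjusted p = 0.071), with a minimum mean of 50 (adjusted p = 0.11), and without DMSO replicate 3 or anlotinib replicate 3 (adjusted p = 0.077 and 0.068). The call of RHOA was lost without any one of DMSO replicates 1, 2 and 3 or anlotinib replicate 2 (adjusted p = 0.077, 0.095, 0.1 and 0.057). That of ROCK2 was lost without DMSO replicate 2 or 3 or anlotinib replicate 2 (adjusted p = 0.086, 0.091 and 0.089) and with scaling by library totals (0.06).

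Of 25 genes of cholesterol synthesis and uptake, 24 rose and 0 fell, also 24 adjusted over the list alone. PMVK, chosen for mention after its value was seen, did not pass (-0.34, limma adjusted p = 0.14). MSMO1, a sterol methyl oxidase, rose 5.45-fold, and SQLE, squalene epoxidase, rose by 1.59 on the log2 scale. The median was 1.84 (camera adjusted p = 1.72e-33; adjusted p = 0.13 with an estimated correlation). Of 35 lysosome and autophagy genes, 22 rose and 0 fell, or 24 adjusted over the list alone. NEU1, a lysosomal sialidase, rose 2.75-fold, RRAGD, a GTPase of nutrient signalling at the lysosome, 2.11-fold, and the autophagy receptor gene SQSTM1 by 0.94 on the log2 scale. The median was 0.45 (camera adjusted p = 3.03e-11; adjusted p = 0.2 with an estimated correlation). Among 21 NRF2 target genes, 11 rose and 0 fell, also 11 adjusted over the list alone. HMOX1, encoding heme oxygenase 1, rose 2.32-fold and the reductase gene AKR1C1 1.88-fold, whereas NQO1 stood at 0.10 (adjusted p = 0.564). AKR1C1 is highly similar in sequence to its paralogs, so its count is uncertain. The median was 0.33 (camera adjusted p = 3.73e-08; adjusted p = 0.13 with an estimated correlation).

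Most tested cell cycle genes fell and most p53 targets rose. Of 35 cell cycle genes, 23 fell and 0 rose, or 28 adjusted over the list alone. MCM6 and MCM4, subunits of the replicative helicase, were 2.86-fold and 3.04-fold lower, and TOP2A, encoding topoisomerase IIα, fell by 1.81. CCNB1, the mitotic cyclin B1, stood at -0.06 (limma adjusted p = 0.817). The median was -0.79 (camera adjusted p = 6.65e-13; adjusted p = 0.3 with an estimated correlation). Of 22 p53 target genes, 19 rose and 2 fell, or 20 and 2 adjusted over the list alone. TP53INP1 rose 4.46-fold, CDKN1A, the cell cycle inhibitor p21, by 1.47 on the log2 scale, and MDM2, the ubiquitin ligase of p53, by 1.61. The genes that fell were TP53I3 and DDB2, named after their values were seen, at -1.05 and -0.26. The median was 0.88 (camera adjusted p = 9.52e-16; adjusted p = 0.13 with an estimated correlation). Replication-dependent histone transcripts, listed as a sign of RNA quality since they mostly lack a poly(A) tail, were higher for 7 of 8 genes, also 7 adjusted over the list alone. HIST1H1C (H1-2) rose 2.86-fold and HIST1H2BK (H2BC12) 2.75-fold, and the list's median was 1.45 (camera adjusted p = 9.48e-07; adjusted p = 0.2 with an estimated correlation).

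Stress genes went in different directions, while the ERK pathway output genes that passed mostly rose. In the list of unfolded protein and amino acid stress genes, 15 of 27 rose and 7 fell, also 15 and 7 adjusted over the list alone. TRIB3, a pseudokinase induced by ATF4, rose 3.08-fold, DDIT3, encoding CHOP, 3.6-fold, and ASNS, asparagine synthetase, by 1.14 on the log2 scale. DDIT3 overlaps other genes on both strands. Endoplasmic reticulum chaperone genes were among those that fell, with PDIA4 at -0.80, CALR at -0.79 and HSPA5 at -0.30. The median was 0.33 (camera adjusted p = 9.54e-05; adjusted p = 0.29 with an estimated correlation). Of 21 ERK pathway output genes, 11 rose and 1, MYC, fell by 0.28, or 15 and 1 adjusted over the list alone. DUSP5, a phosphatase of ERK, rose 1.85-fold, and FOS rose by 1.74 on the log2 scale. The median was 0.39 (camera adjusted p = 4.5e-07; adjusted p = 0.23 with an estimated correlation).

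The remaining lists showed no shift that passed with the settings above, although the mesenchymal and interferon lists passed under others. Of 20 genes for receptors inhibited by anlotinib and their ligands, 4 rose and 6 fell, or 5 and 7 adjusted over the list alone. PGF, placental growth factor, rose 2.63-fold and NRP2, a VEGF co-receptor, was 1.89-fold lower. This list's median was 0.06 while camera placed it lower (adjusted p = 0.691). Of 16 mesenchymal markers, 7 fell and 1 rose, also 7 and 1 adjusted over the list alone, with CDH2, encoding N-cadherin, 2.15-fold lower and TGFB2 1.77-fold lower (median -0.13, camera adjusted p = 0.0786). That list passed with edgeR (adjusted p = 0.032), with library totals (0.037), with a minimum mean of 1 (0.014), with no filter (0.0043) and without DMSO replicate 1 (0.035), but not with an estimated correlation (adjusted p = 0.3). Of 15 epithelial markers, 2 rose and 3 fell, or 2 and 4 adjusted over the list alone. The keratin genes KRT19 and KRT7 were 2.44-fold higher and 2.04-fold lower, and the list's median was -0.04 and its mean 0.01 (camera adjusted p = 0.748). Of 29 interferon response genes, 2 rose and 3 fell, or 1 and 3 adjusted over the list alone, with OAS3 2.23-fold lower and ISG20 1.68-fold higher (median -0.42, camera adjusted p = 0.0786). The call of ISG20 was lost without anlotinib replicate 2 (limma adjusted p = 0.078), and the list passed without DMSO replicate 1 or 3 (camera adjusted p = 4e-04 and 0.03), with library totals (0.037), with a minimum mean of 1 (0.0069) and with no filter (0.0015). Without DMSO replicate 2 its median was 0.00 (adjusted p = 0.86), and with an estimated correlation the list did not pass (adjusted p = 0.78). Of 25 hypoxia and glycolysis genes, 6 rose and 7 fell, or 7 and 8 adjusted over the list alone. The aldolase gene ALDOC rose 5.55-fold and ANGPTL4 was 3.71-fold lower (median -0.10, camera adjusted p = 0.691). Of 20 inflammatory cytokine and NF-κB target genes, 3 rose and 2 fell, also 3 and 2 adjusted over the list alone, the latter being IL11 and the chemokine gene CCL2, which was 2.64-fold lower (median -0.08, camera adjusted p = 0.691; median 0.00 without DMSO replicate 2 and 0.03 without anlotinib replicate 1).

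Measures of sample makeup and RNA quality were compared in the same libraries. Of the markers of fibroblasts, endothelium and blood, 3 were tested, too few for a list test. COL1A1 and THY1, a fibroblast surface marker that was 1.59-fold lower, fell, also when adjusted over the list alone, and CD14 stood at 0.14 (limma adjusted p = 0.645). The call of THY1 was lost without any one of DMSO replicates 1, 2 and 3 or anlotinib replicate 2 (adjusted p = 0.075, 0.069, 0.077 and 0.11). None of 13 mitochondrially encoded genes passed, also when adjusted over the list alone, with MT-ND1 at 0.30 (adjusted p = 0.169) and MT-ND6 at 0.22 (adjusted p = 0.195), and the list's median was 0.14 (camera adjusted p = 0.138). With an estimated correlation the list did not pass either (adjusted p = 0.78). With scaling by library totals the list passed (adjusted p = 0.0075), as did MT-ND1 (0.0091) and MT-ND6 (0.016), and without anlotinib replicate 3 so did the list (adjusted p = 0.00058), MT-ND1 (0.0098) and MT-ND6 (0.03). The list also passed with limma-voom (adjusted p = 0.046) and MT-ND1 with DESeq2 (adjusted p = 0.046). The other list of RNA quality, replication-dependent histone transcripts, was higher for 7 of 8 genes, with a median of 1.45 (camera adjusted p = 9.48e-07; adjusted p = 0.2 with an estimated correlation). Mitochondrial genes held 9.83% ± 1.08 of reads with anlotinib and 8.39% ± 0.509 with DMSO (SD, n = 3; exact two-sided permutation p = 0.2, where 0.1 is the smallest possible). More genes had at least 1 read in the anlotinib libraries, with 24594, 25881 and 27183 against 23993, 23903 and 23865 with DMSO (exact two-sided permutation p = 0.1).

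In all, 14 of 21 lists passed with camera at a preset correlation of 0.01, and 0 passed with an estimated correlation, where 5 had an unadjusted p under 0.05. With the self-contained test fry, which does not compare a list with other genes, 12 lists passed. Matrix glycoproteins (adjusted p = 0.068), remodelling enzymes (0.085) and the RhoA/ROCK list (0.054) did not pass with fry, and mesenchymal markers did (0.016).

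**Figure D3:**
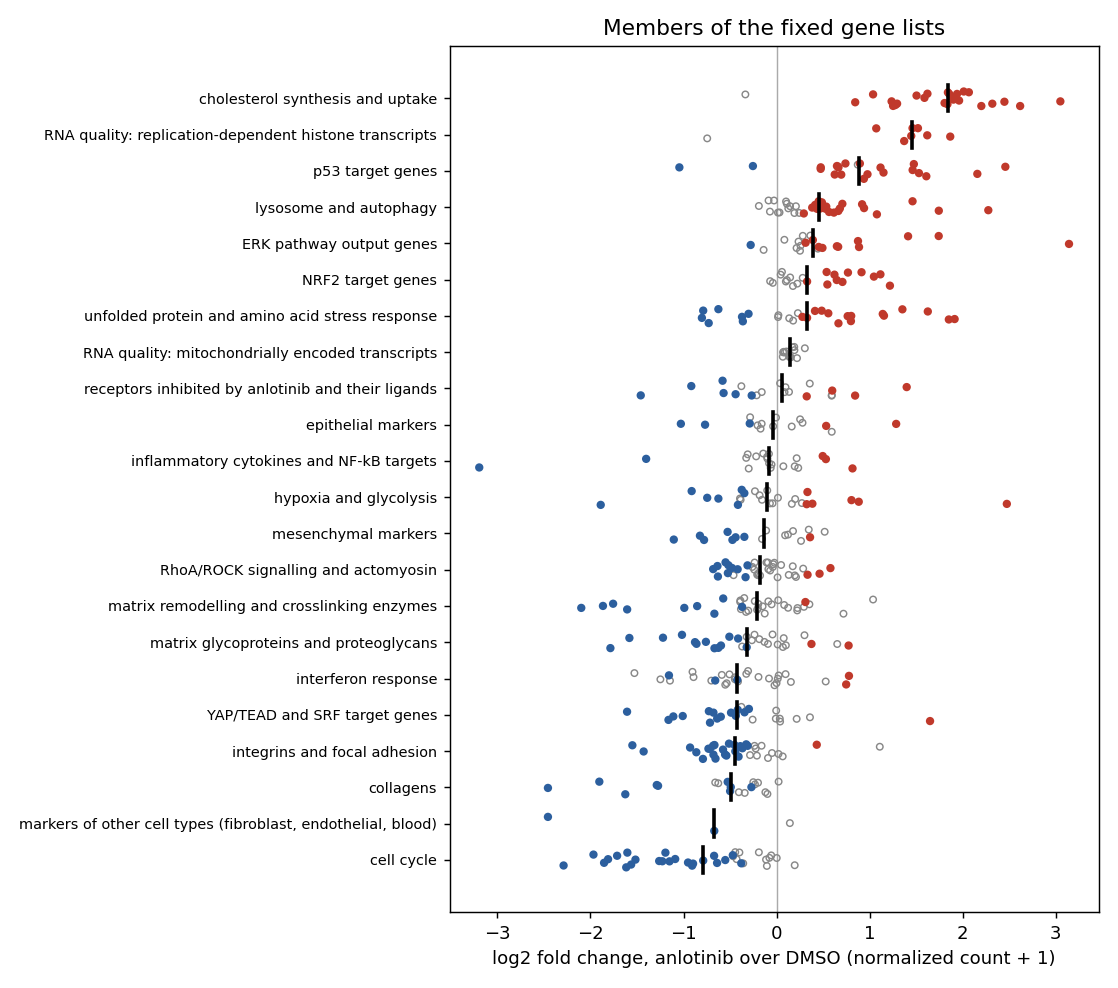
Log2 fold change, anlotinib over DMSO, of each tested member of the fixed lists; filled points passed at an adjusted p under 0.05 (red higher, blue lower), open points did not, and black bars are list medians. Medians run from -0.79 for cell cycle genes to 1.84 for cholesterol synthesis and uptake.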

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

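The minimum mean of 1 and TMM scaling were chosen after seeing the data. Over all alternatives 0 shared calls changed direction. Leaving out single libraries gave 1972 to 5487 changed genes, 646 to 1053 changed at least 2-fold, 14 to 16 lists and 45 to 51 of the named genes; fewer samples were tested, but the cause of the higher count without anlotinib replicate 1 was not tested. A minimum mean of 50, which tests fewer genes, gave 486 genes changed at least 2-fold against 829, with 202 higher and 284 lower against 465 and 364. Other settings gave 3179 to 3765 changed genes. With an estimated correlation 0 lists passed, against 14 with camera's preset correlation, 5 at an unadjusted p under 0.05 and 12 with fry. Of the log2 fold changes that did not pass, ROCK1 turned from -0.04 to 0.04 with scaling by library totals, to 0.03 without DMSO replicate 3 and to 0.07 without anlotinib replicate 1, with a range of -0.11 to 0.07 when single libraries were left out. The list of receptors and ligands turned higher with a minimum mean of 1 (median 0.09), the interferon list without DMSO replicate 2 (median 0.00, range over left-out libraries -0.66 to 0.00), and the inflammatory list without DMSO replicate 2 (0.00) or anlotinib replicate 1 (0.03; range -0.19 to 0.03); the cause was not tested. The interferon list passed without DMSO replicate 1 (adjusted p = 4e-04) or 3 (0.03), with library totals (0.037), a minimum mean of 1 (0.0069) and no filter (0.0015), but not with an estimated correlation (0.78) or without DMSO replicate 2 (0.86). Mesenchymal markers passed with edgeR (0.032), library totals (0.037), a minimum mean of 1 (0.014), no filter (0.0043) and without DMSO replicate 1 (0.035), but not with an estimated correlation (0.3). The labels do not say whether equal replicate numbers pair the samples. The deviations of same-numbered libraries correlated at -0.04, 0.03 and 0.00, so no shared effect of replicate number was seen. With a replicate block 3552 genes changed, 816 of them at least 2-fold, and 14 lists and 49 named genes passed; the RhoA/ROCK list did not (adjusted p = 0.052) and the interferon list did (0.045). The real grouping gave 3648 changed genes, 829 at least 2-fold and 14 lists. Across the 9 other splits of the 6 libraries the highest values were 0, 0 and 12, with limma calling 86 to 702 genes at an unadjusted p under 0.05 and camera 6 to 12 lists. In each case 1 of 10 splits, the real one, gave a value as large, and 10 splits are too few for a share under 0.05. Every other split mixes treatments within its groups, so the treatment effect widens the spread there. These splits therefore do not show how many calls arise without an effect. At a depth of 13886120 to 15386107 reads, simulated changes of 0.5 on the log2 scale were recovered for 43 of 100 genes. The simulation changed far fewer genes than were called here and gave both groups the same spread. Its recovery is therefore not the sensitivity of the real comparison.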

Other observations

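The gene lists in this part were written after a first look at the results. The tests of depth, of tubulin copies, of dividing cells, of genes matched in length and GC content and with single libraries left out were chosen after the values they use were seen. Genes of α- and β-tubulin, the subunits of microtubules, fell in 10 of 12 cases (limma, adjusted p under 0.05; also 10 adjusted over the list alone), with a median of -1.43 (camera adjusted p = 1.54e-09; adjusted p = 0.12 with an estimated correlation). TUBA4A fell by 2.67, TUBB by 2.11 and TUBA1B by 1.94 on the log2 scale, while the neuronal isotype gene TUBB3 stood at 0.04 (adjusted p = 0.89). Of 14 genes for other tubulins and tubulin cofactors, 3 fell, with a median of -0.23 (camera adjusted p = 0.0194; adjusted p = 0.3 with an estimated correlation). Fatty acid synthesis genes rose in 10 of 15 cases and 1 fell, with a median of 0.50 (camera adjusted p = 1.12e-07; adjusted p = 0.12 with an estimated correlation). FASN, the fatty acid synthase, rose by 1.10 and the desaturase gene FADS2 by 1.52, whereas ACLY stood at -0.26 (adjusted p = 0.11). Of 7 LXR target genes, 2 rose, APOE by 1.88 and SMPDL3A by 0.75, and the list did not pass (camera adjusted p = 0.252; median 0.03).

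Within the cell cycle list, all 14 replication genes fell (median -1.25; camera adjusted p = 1.9e-13; adjusted p = 0.12 with an estimated correlation), and 8 of 20 mitotic genes fell (median -0.44; camera adjusted p = 0.000116; adjusted p = 0.37 with an estimated correlation). The list was split in this way after its values were seen, so a p-value for the difference would restate the split, and CCNA2, which also fell (-0.55), was placed in neither part.

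The fall of the α- and β-tubulin genes was weighed against reads moving between near-identical copies. The summed normalized counts of these genes had a log2 ratio of -1.74, a 3.33-fold lower level with no overlap between groups. This argues against a move among the listed genes. Tubulin pseudogenes were not in the sum, so a move of reads to them was not tested. A smaller share of dividing cells stays open: the tubulin genes lay below the mitotic genes by a median of -0.99 (permutation, one-sided p = 0.0084, adjusted p = 0.011) but not detectably below the replication genes (-0.19, p = 0.32). Tubulin autoregulation, in which free tubulin speeds decay of α- and β-tubulin mRNA, stays open too: these genes lay below other tubulins and cofactors by -1.20 (permutation, one-sided p = 0.00029, adjusted p = 0.0012), but 3 of those 14 genes fell too, and whether that list was lower is unsettled (camera adjusted p = 0.0194; adjusted p = 0.3 with an estimated correlation). The α- and β-tubulin list was written because its genes had been seen to fall, so these p-values, which also treat genes as independent, largely restate that fall.

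The fall of matrix, integrin and actin-linked genes was weighed against a bias of gene length and GC content. Genes outside these lists but matched to their members in both had medians of -0.04 for collagens, -0.03 for integrins and focal adhesion and -0.02 for YAP/TEAD and SRF targets, with 95% ranges over matched sets above the bootstrap 95% intervals of the lists (upper ends -0.25, -0.29 and -0.26), which argues against that bias as the whole cause there. For matrix glycoproteins, remodelling enzymes and the RhoA/ROCK list the matched medians were 0.01, -0.04 and -0.01. There 0, 7 and 14 of 2000 matched sets were as low as the list. Few sets of other genes with like length and GC content thus had so low a median. The matched ranges still overlapped the lists' bootstrap intervals, so the test does not decide there. For every list, the matched sets and the intervals treat genes as independent, which may overstate the contrast for genes that vary together. For all 6 lists together the matched range was -0.09 to 0.04 against a list interval of -0.38 to -0.24. A loess correction, which moved genes by -0.08 to 0.05, decides nothing. As a hypothesis, lower output of TGF-β signalling may contribute: 8 of 15 TGF-β target genes fell and 0 rose (median -0.34; camera adjusted p = 0.00068; adjusted p = 0.2 with an estimated correlation). This rests on the preset correlation, and of the 12 genes other than TGFBI, SMAD7 and TGFB1, which the fixed lists share, 5 fell (median -0.20; camera adjusted p = 0.019 over 8 lists).

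Genes with a mean under 10 normalized counts took 0.196%, 0.257% and 0.336% of reads in the anlotinib libraries and 0.202%, 0.182% and 0.182% in the DMSO libraries (exact two-sided permutation p = 0.2). Lower depth of the DMSO libraries is argued against, since at an equal depth of 13886120 reads the lowest anlotinib library still had 330 more such genes with a read than the highest DMSO library. For more unspliced or antisense RNA of expressed genes, a ratio above 2 was set as the sign. Expressed genes were here those with a mean of at least 100 normalized counts, so other low genes could overlap genes expressed below that. The excess per kb in low genes that overlap expressed genes was 0.97 times that in other low genes. The bootstrap 95% interval was 0.83 to 1.12, and the ratio was 0.22 to 1.25 with single libraries left out. The ratio stayed below 2, but the unknown counting could drop or share reads where genes overlap, so this does not decide. Genomic DNA in the treated RNA, which would add about equally to both, stays open: the ratio of 0.97 rests on anlotinib replicate 3, without which it was 0.22 (0.05 to 0.4), the excess over all low genes was 5244 in place of 8892 normalized counts, and that per kb was 0.0513 in place of 0.308 inside expressed genes and 0.231 in place of 0.317 elsewhere; without anlotinib replicate 1 these values rose to 1.25 (1.13 to 1.39), 12579, 0.524 and 0.419. A wider low-level transcription after anlotinib was not tested and stays open.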
